A study of Mus musculus with 7 samples.

How the data were processed

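Small RNAs were sequenced from cell populations sorted by fluorescence from dissociated mouse embryonic spinal cord. Per the labels' protocols, tissue was dissociated with papain, total RNA was extracted with a miRvana kit, libraries were made with a NEBNext small RNA kit and sequencing was on HiSeq instruments. At E10.5, GFP-positive and GFP-negative cells of Hb9::gfp embryos gave 2 motoneuron and 2 non-motoneuron libraries. At E12.5, Hb9::gfp motoneurons, V2a interneurons (Chx10::cre with a Cre-dependent tdTomato reporter) and V3 interneurons (Sim1::cre with the same reporter) gave 1 library each. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate litters or sorts, so p-values measure the spread between these libraries, which may be technical.

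Bowtie2 is named in the submitters' processing notes, with no version. The counting program, the genome build and the miRNA annotation are not given in the sources used here. The E10.5 table as deposited holds RPM values for 1908 mature miRNAs, and each library sums to 1000000. It also holds the authors' mean of each group and the authors' ratio of the 2 means, which is a fold on a linear scale. Those means matched the mean of the library columns to within 0.005. The file groups rows into 1793 bundles, of which 1724 hold a single row. The remaining 184 rows, such as let-7 members, miR-10a and miR-10b, or miR-199a and miR-199b, lie in bundles of several rows. In the deposited RPM values, 97.5% to 100.0% of low values in single-row bundles lay within 0.05 of a whole multiple of the RPM of 1 read, against 87.4% to 90.0% over all rows. Fractions of reads thus sat in the shared bundles, and values of near-identical miRNAs are uncertain.

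The E12.5 table as deposited names no unit. Its values were read as FPKM, as the authors deposited them, because low values fell on steps in the ratio of lengths near 22 nt. Of 791 rows checked, 60.7% were whole reads in all 3 libraries at a single length between 16 and 28 nt, against 22.0% after shuffling. Each E12.5 library was rescaled to a sum of 1000000, which gives TPM. The 2 tables were scaled separately, so groups were tested only within a table. The closing section also takes ratios of E10.5 over E12.5 levels for some miRNAs, without a p-value, where stage and table cannot be told apart.

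The RPM of 1 read gave depths of 777479 and 538640 reads for the E10.5 non-motoneuron libraries and 802747 and 493233 for the E10.5 motoneuron libraries. With 22 nt as the length, the E12.5 depths were about 3603500 reads for motoneurons, 4605324 for V2a and 4270037 for V3. A count of 0 allows up to 3 reads, which is 3.74 to 6.08 RPM at E10.5 and 0.67 to 0.84 TPM at E12.5. Counting intervals, Fisher's exact tests on reads and these floors cover counting error only, since PCR copies are not independent molecules. The 10 most abundant miRNAs held 45.9% to 63.4% of reads at E10.5 and 70.5% to 80.7% at E12.5.

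The count-based test planned before the data were examined was not used, because the table holds RPM. The E10.5 groups were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided) on log2(RPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. miRNAs were tested if they reached 15.2 RPM, which is 10 reads at the median depth, in at least 2 libraries. Fold changes on this scale understate the change of low miRNAs. On simulated reads for 492 miRNAs with 200 changed, over 20 runs, the procedure called 61.3% of 2-fold, 95.8% of 4-fold and 98.3% of 8-fold changes, and 2.45% of calls were false. The simulation used a dispersion of 0.04, so these rates hold for that setting only.

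Members of 17 lists of miRNAs, written before the data were examined, were compared with all other miRNAs by limma's camera with a preset correlation of 0.01. The planned fry test of limma took the members of each list alone, without comparison with other miRNAs. The lists were the miR-218 family, pan-neuronal miRNAs, neural progenitor miRNAs, miRNAs tied to motoneurons in earlier literature, the miR-17~92 and paralogous clusters, let-7, the miR-99/100 and miR-125 families, the Hox clusters, the Dlk1-Dio3 cluster and pluripotency miRNAs. For other cell types they were the blood, endothelial, mesenchymal, muscle, epithelial, sensory neuron and oligodendrocyte lists. One list had a single tested member, so 16 were tested. As an alternative, camera estimated the correlation within each list. Estimates ran from -0.36 (oligodendrocyte list) to 0.99 (muscle list), so the preset of 0.01 takes little account of members that vary together. With 4 libraries the estimate leaves few degrees of freedom, and no list passed, not even the mesenchymal one. Failing this alternative thus does not tell lists apart.

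E12.5 libraries have no replicates and were only described. A miRNA counted as higher or lower in 1 population when it lay at least 4-fold above or below each of the other 2 libraries, on the TPM + 1 scale, and reached 10 TPM in at least 1 library. The median ratio of each list was placed among 10000 random lists of the same size matched on mean abundance. On 100 simulated lists of 10 among 523 miRNAs, a shift by 1 log2 unit put 66% above the 97.5th percentile, and 5% of unshifted lists fell outside the central range. These steps used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6, and figures used matplotlib 3.10.9.

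The miRNAs named were fixed by rule: the miR-218 family always; at E10.5 the 10 largest changes in each direction with non-overlapping groups, the 5 most abundant of each group and up to 3 abundant members of each list; at E12.5 up to 10 motoneuron-high and 10 motoneuron-low miRNAs, up to 5 each for V2a and V3, and the 5 most abundant of each library. Others are said to be chosen after their values were seen. Positions of hairpins are those of the same-named genes in GENCODE M21 (GRCm38), 1-based, since the files give none. Alternatives changed the scaling, filter, pseudocount, tool, treatment of shared bundles and libraries used, and the closing section gives their effect.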

Results

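Small RNA abundance was measured in 7 libraries of sorted embryonic mouse spinal cells. The E10.5 set held 2 libraries of Hb9::gfp-positive motoneurons and 2 of GFP-negative cells from the same reporter line, in which GFP marks Hb9-expressing motoneurons. The E12.5 set held 1 library each of motoneurons, V2a interneurons and V3 interneurons. Depths ran from 493233 to 802747 reads at E10.5 and from about 3603500 to 4605324 at E12.5. Replicates had a Pearson correlation across tested miRNAs of 0.984 in the non-motoneuron group and 0.975 in the motoneuron group, against 0.844 to 0.878 between groups.

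The first comparison asked how far miR-218, named in the series title as motoneuron-specific, separated motoneurons from other spinal cells at E10.5. miR-218-5p was the most abundant miRNA of the motoneuron libraries, at 189095 ± 15853 RPM (SD, n = 2), against 6969 ± 489 (SD, n = 2) in GFP-negative cells. The 27.1-fold difference was a log2 fold change of 4.76 (SE 0.14, limma adjusted p = 4.24e-06). The ratio in the authors' deposited table was also 27.1. The passenger strand miR-218-2-3p stood at 57.6 ± 15.5 RPM in motoneurons and 2.79 ± 3.94 in GFP-negative cells, a log2 fold change of 4.49 (SE 0.86, limma adjusted p = 0.00625). Its GFP-negative libraries held 0 and 5.57 RPM, so the log2 fold change was 3.13 without non-motoneuron replicate 1 and 5.85 without replicate 2, and without either motoneuron replicate it missed the abundance filter. miR-218-1-3p was below the abundance filter, at 3.74 and 6.08 RPM in the motoneuron libraries and 0 in both GFP-negative libraries. The mature 5p strand can come from both hairpins. Mir218-1 lies on chromosome 5 at 48223942 to 48224051 on the plus strand, in an intron of Slit2. Mir218-2 lies on chromosome 11 at 35616816 to 35616925 on the plus strand, in an intron of Slit3.

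**Figure D1:**
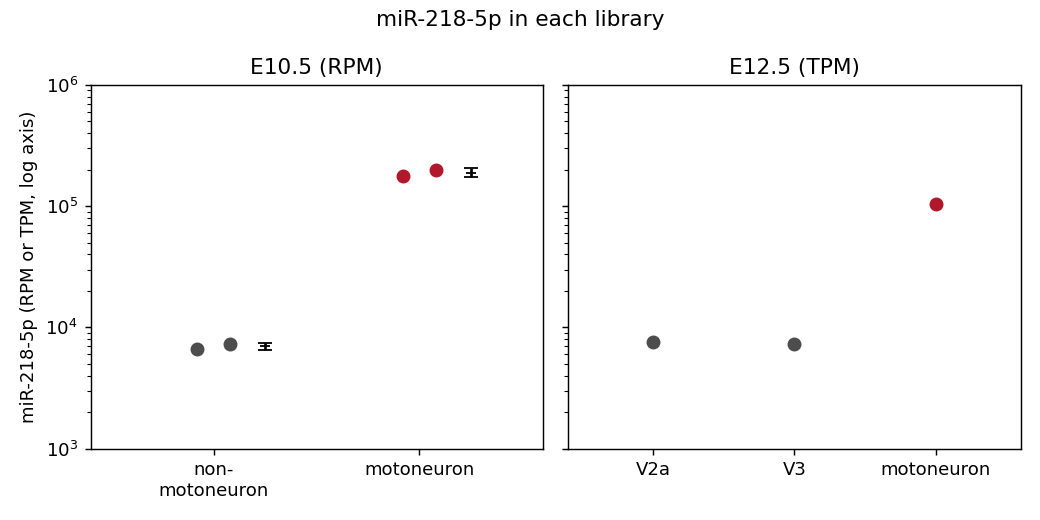
miR-218-5p in each library on a log axis, as RPM at E10.5 (left, 2 libraries per group, with mean and SD beside the points) and as TPM at E12.5 (right, 1 library per group). The E10.5 motoneuron libraries had 177885 and 200305 RPM, and the E12.5 motoneuron library had 104198 TPM against 7558 in V2a and 7282 in V3.

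The wider E10.5 comparison asked which other miRNAs separate motoneurons from GFP-negative cells. Among 492 miRNAs tested, 57 were higher and 151 lower in motoneurons (limma adjusted p under 0.05), and 259 passed an unadjusted p of 0.05. With either motoneuron replicate left out, fewer miRNAs were called higher. Such a fit also drops from testing the miRNAs that pass the filter only through the 2 motoneuron libraries, which by itself lowers that count. In all 208 called miRNAs the libraries of the 2 groups did not overlap. Without overlap, 123 tested miRNAs were higher and 239 lower, where chance gives 33.3% of miRNAs in total. The median log2 fold change over all tested miRNAs was -0.34. Scaling by the median of ratios put that median at 0.01 and gave 94 higher and 115 lower, TMM factors on RPM gave 103 and 118, totals without the 5 most abundant miRNAs gave 108 and 116, and quantile normalization gave 114 and 100. Totals without the mesenchymal and muscle lists moved the split the other way, to 42 and 165. The split between higher and lower thus depended on the scaling.

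After miR-218, the largest rises were in miR-6540-5p, miR-7a-2-3p, both strands of Mir3085, miR-3078-3p, miR-124-3p, miR-302c-3p and miR-466i-3p. miR-6540-5p reached 1171 ± 102 RPM against 164 ± 44.2 (log2 fold change 2.85, SE 0.25, limma adjusted p = 0.000436). Its hairpin lies on chromosome 16 at 42303362 to 42303469 on the minus strand, in an intron of Gap43, a growth cone protein gene. Of the rest, miR-7a-2-3p rose by 2.57, miR-3085-3p by 2.55, miR-3085-5p by 2.35, miR-3078-3p by 2.17, miR-302c-3p by 1.99 and miR-466i-3p by 1.89 on the log2 scale. miR-302c-3p and miR-466i-3p share reads with other rows. miR-7a-2-3p, miR-3085-5p, miR-3078-3p and miR-302c-3p passed the abundance filter only in the motoneuron libraries, so without either motoneuron replicate they were not tested. The GFP-negative libraries held 3.86 and 14.85 RPM of miR-3078-3p. With only rows at 0 in all libraries removed, miR-3085-5p, miR-3078-3p and miR-302c-3p no longer passed the threshold.

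Of 11 pan-neuronal miRNAs tested, 6 were higher and none was lower (camera adjusted p = 0.00089, adjusted p = 0.477 with an estimated correlation, 7 called when adjusted over the list alone). Fewer of them were called higher with any 1 library left out. Without a motoneuron replicate, miRNAs that pass the filter only through motoneurons were also no longer tested. With only all-zero rows removed, 3 pan-neuronal miRNAs were called higher. miR-124-3p, a pan-neuronal miRNA, was at 375 ± 98.0 RPM against 84.7 ± 14.8 (log2 fold change 2.12, SE 0.29, limma adjusted p = 0.00181). miR-7b-5p and miR-7a-5p, which share reads, rose by 0.59 and 0.49, while miR-128-3p had a log2 fold change of 0.01. Of 4 neural progenitor members, 1 was higher, miR-92b-3p (0.51), and 0 when adjusted over the list alone (camera adjusted p = 0.0425, adjusted p = 0.477 with an estimated correlation). miR-9-5p had 0.38 (limma adjusted p = 0.124). With the median of ratios, TMM factors or totals without the 5 most abundant miRNAs, 3 of the 4 were higher. The list did not pass with fry (adjusted p = 0.169). The progenitor list also no longer passed under quantile normalization (camera adjusted p = 0.128), with 1 arm per hairpin (0.111) or without motoneuron replicate 1 (0.0707) or non-motoneuron replicate 2 (0.217). Of 3 members of the oligodendrocyte list, miR-219a-2-3p rose by 1.13 and miR-219a-5p by 0.92 (camera adjusted p = 0.025, adjusted p = 0.477 with an estimated correlation, 0.0743 under quantile normalization). The members share reads with other rows, and 1 was higher with shared rows summed.

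Of the 9 Hox-cluster miRNAs, which lie among the Hox genes, 3 were higher (camera adjusted p = 0.00874, adjusted p = 0.477 with an estimated correlation). The fry adjusted p was 0.0922. The list no longer passed under quantile normalization (camera adjusted p = 0.137, 3 higher and 1 lower) or without non-motoneuron replicate 2 (0.0859), and 5 were higher without non-motoneuron replicate 1. miR-615-3p, from an intron of Hoxc5 (chromosome 15, 103014910 to 103015001), stood at 42467 ± 963 RPM against 20813 ± 1217, a log2 fold change of 1.03. The very abundant miR-10a-5p and miR-10b-5p, which share reads, had log2 fold changes of 0.28 and 0.08 and did not pass the threshold. miR-10b-5p reversed its sign under quantile normalization. In the miR-99/100 and miR-125 families, 2 of 9 members were higher, miR-99a-5p (0.67) and miR-100-5p (0.66). These 2 share reads, and 1 member was higher with shared rows summed. Without motoneuron replicate 1, the log2 fold changes of miR-99a-5p and miR-100-5p were 0.84 and 0.75. That family's median was -0.20 as deposited and 0.15 with the median of ratios, and its test, which pointed up, did not pass (camera adjusted p = 0.519).

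**Figure D2:**
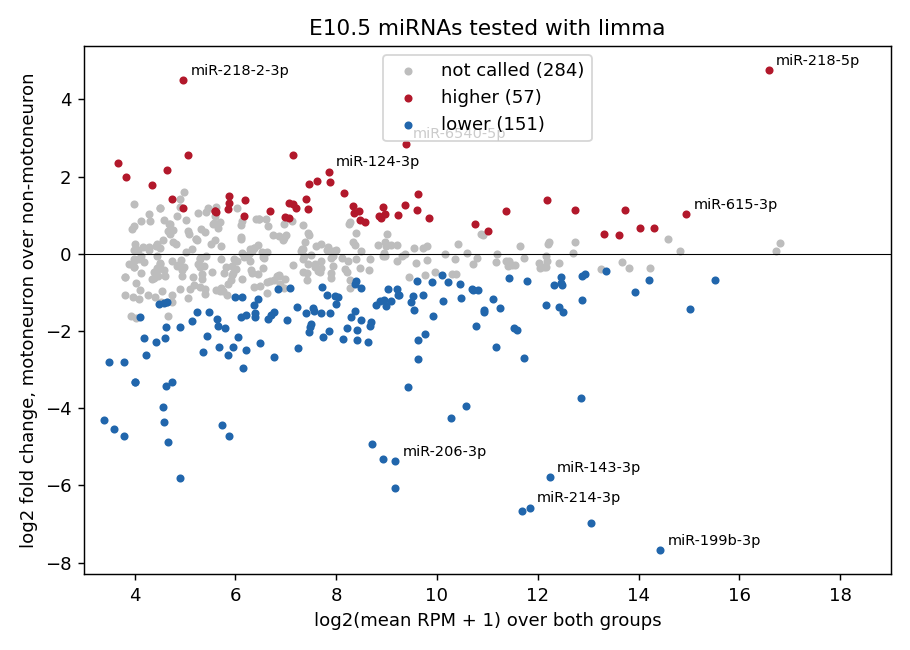
log2 fold change of each tested miRNA (motoneuron over non-motoneuron) against its mean abundance on a log2 scale at E10.5. The 57 higher miRNAs are red and the 151 lower miRNAs blue, and miR-218-5p combines the largest rise with the highest motoneuron abundance.

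The largest falls were in miRNAs of mesenchymal and muscle tissue. All 10 mesenchymal and smooth muscle members were lower (camera adjusted p = 2.33e-05, adjusted p = 0.477 with an estimated correlation), with a median log2 fold change of -5.94, or -5.92 with miR-145a-3p at its bound. Their summed abundance was 81413 and 94290 RPM in the GFP-negative libraries and 1571 and 424 RPM in the motoneuron libraries. miR-199b-3p stood at 43954 ± 4165 RPM in GFP-negative cells and 314 ± 327 in motoneurons (log2 fold change -7.68, SE 0.75, or -9.03 and -6.33 without motoneuron replicate 1 and 2). miR-199b-5p, miR-199a-5p, miR-214-3p, miR-214-5p and miR-143-3p had log2 fold changes of -6.98, -6.66, -6.58, -6.06 and -5.78. The miR-199a and miR-199b rows of each strand share reads, so the split between them is uncertain. With the median of ratios miR-199b-3p had -7.33 and miR-199a-3p -3.91. miR-145a-3p was 0 in both motoneuron libraries and at least 11.8-fold lower than in GFP-negative cells. Mir214 and Mir199a-2 lie on chromosome 1 in exons of Dnm3os, starting at 162223368 and 162217814. Of the muscle miRNAs, 3 of 3 tested were lower, among them miR-206-3p (-5.37) and miR-1a-3p (-3.95), which share reads (camera adjusted p = 0.0425, adjusted p = 0.477 with an estimated correlation). The fry adjusted p was 0.0544. The muscle list no longer passed with shared rows summed (camera adjusted p = 0.103) or 1 arm per hairpin (0.0543). miR-206-3p stood at 71.3 and 8.95 RPM in the motoneuron libraries, and its log2 fold change was -6.80 without replicate 1 and -3.94 without replicate 2 of motoneurons. Both strands of Mir483, miR-483-3p (-5.31) and miR-483-5p (-4.93), were also far lower.

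The 3 sensory neuron members were lower, with log2 fold changes of -2.41 for miR-182-5p, -1.99 for miR-183-5p and -1.71 for miR-96-5p (camera adjusted p = 0.0213, adjusted p = 0.477 with an estimated correlation). In the miR-17~92 and paralogous clusters, linked to proliferation, 13 of 22 members were lower and none higher (camera adjusted p = 0.0262, adjusted p = 0.477 with an estimated correlation). That list no longer passed with shared rows summed (camera adjusted p = 0.0904), under quantile normalization (0.0743, 6 lower and 2 higher) or without motoneuron replicate 2, with 7 lower (0.0828). With the median of ratios, TMM factors or totals without the 5 most abundant miRNAs, 8 were lower. miR-20a-5p stood at 17888 ± 1228 RPM against 48177 ± 3438, and miR-92a-3p at 36073 ± 1111 against 58245 ± 8366. The fall of miR-92a-3p was no longer called with the median of ratios (-0.34). Of 15 let-7 members, 10 were lower (camera adjusted p = 0.0372, adjusted p = 0.529 with an estimated correlation, 12 called when adjusted over the list alone), among them let-7a-5p (-0.81) and let-7g-5p (-1.16). The let-7 rows share reads, and the list no longer passed with shared rows summed (camera adjusted p = 0.209, 3 lower), under quantile normalization (0.137, 6 lower and 3 higher), with 1 arm per hairpin (0.111) or without motoneuron replicate 1 (0.0842). Nor did it pass without non-motoneuron replicate 1 (camera adjusted p = 0.0679) or 2 (0.196, 6 lower).

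In the Dlk1-Dio3 imprinted cluster, 32 of 69 members were lower and 1 was higher (camera adjusted p = 0.00089, adjusted p = 0.477 with an estimated correlation), among the lower ones miR-541-5p (-1.0) and miR-127-3p (-0.68), while the most abundant member, miR-370-3p, had a log2 fold change of 0.08. With the median of ratios 20 members were lower and 2 higher, without miR-127-3p. Of other settings, the lower count was 22 without motoneuron replicate 2, and quantile normalization gave 16 lower and 2 higher. Of 7 miRNAs tied to motoneurons in earlier literature, 5 were lower, with miR-27b-3p at -1.93 and miR-17-3p at -1.06, and the list missed the threshold (camera adjusted p = 0.0559, 6 called when adjusted over the list alone). It passed as lower with the median of ratios (camera adjusted p = 0.0411), TMM factors (0.0390), totals without the 5 most abundant miRNAs (0.0421), quantile normalization (0.0323) and only all-zero rows removed (0.00221). With an estimated correlation its camera adjusted p was 0.477. Its fry adjusted p was 0.00893, which passed. The list's median log2 fold change was -1.92, or -1.44 and -1.46 without non-motoneuron replicate 1 and 2. Pluripotency miRNAs had 1 of 7 higher (camera adjusted p = 0.327), the 2 blood miRNAs were not called (camera adjusted p = 0.762) and 1 of 4 epithelial miRNAs, miR-200b-3p, was lower (camera adjusted p = 0.307). The endothelial miR-126a-3p had a log2 fold change of -1.07, called as lower but not with the median of ratios.

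**Figure D3:**
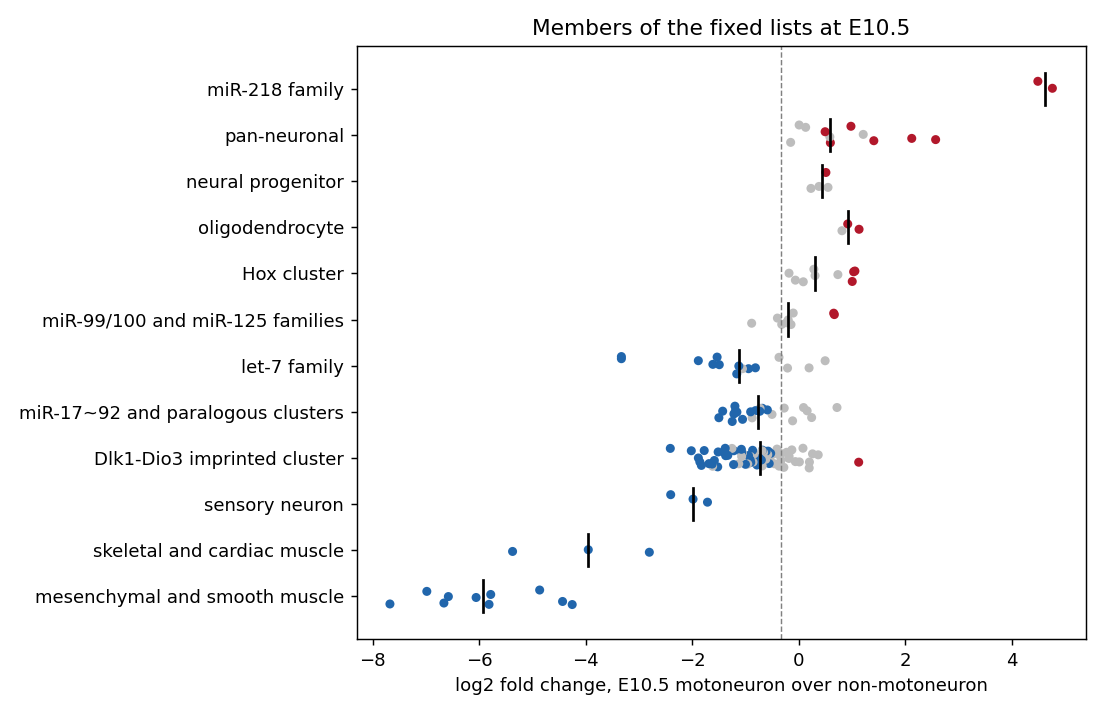
log2 fold change at E10.5 of each tested member of 12 fixed lists, with called members in red or blue, other members in gray, a black bar at each list's median and a dashed line at the median of all tested miRNAs, -0.34. The mesenchymal list has the lowest median, -5.94, and the 2 miR-218 members farthest to the right.

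The third comparison asked whether miR-218 also separates motoneurons from other neurons at E12.5, in single libraries with no replicate check. miR-218-5p reached 104198 TPM in motoneurons, 7558 in V2a and 7282 in V3, a 13.8-fold and a 14.3-fold difference. miR-218-2-3p was at 17.4 TPM in motoneurons and 0 in V2a, at least 26.0-fold higher. Against V3, with 3 reads there, the ratio was 24.2 (95% counting interval 8.0 to 122). miR-218-1-3p was nearly level, at 2.53, 1.78 and 2.16 TPM in motoneurons, V2a and V3.

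Of 523 miRNAs considered at E12.5, 9 were higher and 5 lower in motoneurons than in both interneuron libraries, or 3 and 0 with a pseudocount of 10. Besides miR-218 the higher ones were miR-139-5p (173 against 16.2 in V2a and 11.3 in V3), miR-139-3p (26.2 against 4.23 and 1.44), miR-490-3p (28.98 against 4.45 and 2.64), miR-369-3p (3847 against 887 and 374), miR-129-2-3p (13.3 against 0.67 and 0.20), miR-6948-3p (11.2 against 0.47 and 1.01) and miR-3059-5p (10.98 against 0 in both, at least 15.2-fold). Mir139 lies in an intron of Pde2a (chromosome 7, 101475376 to 101475443) and Mir490 in an intron of the muscarinic receptor gene Chrm2 (chromosome 6, 36421742 to 36421825). miR-206-3p was lower, at 4.50 TPM against 175 in V2a and 32.9 in V3. The other lower ones were miR-219c-5p, miR-7684-3p, miR-7687-5p and miR-1193-5p, all under 35 TPM in every library. Of the miRNAs in this paragraph, miR-129-2-3p, miR-206-3p and miR-219c-5p lie in bundles of several rows, so their values are uncertain.

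**Figure D4:**
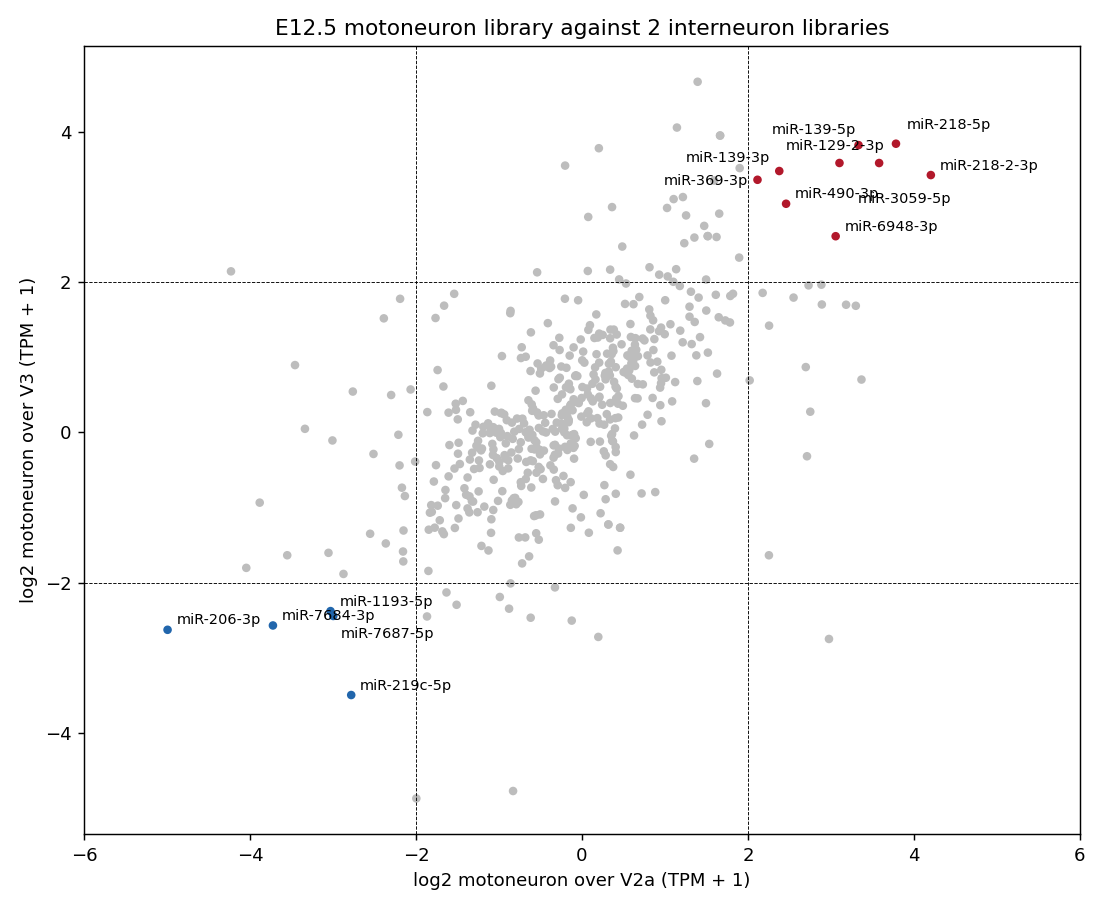
log2 ratio of the E12.5 motoneuron library over V2a (horizontal) and over V3 (vertical) for 523 miRNAs, from TPM plus 1, with 1 library per population. Dashed lines mark the 4-fold rule, and the 9 red and 5 blue points passed it against both interneuron libraries.

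The V2a library had 14 higher miRNAs (8 with the median of ratios or TMM factors, 7 with a pseudocount of 10), led by miR-344e-3p (699 TPM against 36.3 in motoneurons and 7.45 in V3), miR-449a-5p (44.04), miR-219b-3p (24.5), miR-6396 (196) and miR-216a-5p (152). The V3 library had 5, namely let-7b-5p (1585 against 240 in motoneurons and 209 in V2a), miR-128-1-5p (366), miR-375-3p (291), miR-483-5p (41.6) and miR-1966-5p (14.4). The commonest miRNAs were shared: miR-10a-5p was at 128052, 249133 and 220124 TPM in motoneurons, V2a and V3, miR-10b-5p at 164403, 176399 and 167569, and miR-9-5p at 73278, 73931 and 160334. miR-99a-5p was higher in motoneurons (53775 against 30328 and 28230), and miR-615-3p lower (51662 against 92772 and 96727), each by less than 4-fold. miR-219b-3p, let-7b-5p, miR-10a-5p, miR-10b-5p and miR-99a-5p lie in bundles of several rows.

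Among lists at E12.5, the 62 Dlk1-Dio3 members had a median log2 ratio of 0.70 in motoneurons over the mean of both interneurons, above all 10000 random lists. Their median was 0.52 against V2a and 0.82 against V3, and 47 of the 62 lay above both. Random lists hold miRNAs drawn independently, so percentiles take no account of members of 1 cluster that vary together. The 17 pan-neuronal members had a median of 0.87 (percentile 99.7). The 2 blood miRNAs had a median of 1.52 (percentile 96.5), but only 1 of the 2 lay above both interneurons. All annotated members of the blood list summed to 124.9, 57.1 and 18.1 TPM in motoneurons, V2a and V3. Among lists with at least 2 members, the lowest median was that of the 2 muscle miRNAs (-1.02, percentile 7.24). These 2 share reads and went opposite ways, miR-206-3p at -3.81 and miR-1a-3p at 1.76. The 2 sensory neuron miRNAs had -0.54 (percentile 15.5) and the 5 mesenchymal miRNAs -0.45 (percentile 17.8). The epithelial list had 1 member, at -2.36 against V2a and -1.48 against V3. Medians low among random lists were those of neural progenitor miRNAs (-0.86, percentile 0.60), let-7 (-0.42, percentile 1.11) and Hox miRNAs (-0.41, percentile 3). The let-7 median was 0.03 against V2a and -0.87 against V3, and the progenitor median -0.32 and -1.39. The 19 proliferation members had -0.16 (percentile 20.02), the miR-99/100 and miR-125 members 0.55 (percentile 89.0), the 7 of the earlier literature -0.36 (percentile 17.7) and the oligodendrocyte members 0.30 (percentile 65.5). Mesenchymal miRNAs summed to 199, 249 and 310 TPM in motoneurons, V2a and V3. These describe 3 libraries, and the counts moved with the fold rule, the abundance minimum, the pseudocount and, for V2a, the scaling.

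The last comparison asked whether the same miRNAs separated motoneurons from other cells at both stages. miR-218-5p and miR-218-2-3p did, along with miR-6540-5p (508 TPM against 161 and 175), miR-139-3p, miR-149-5p, miR-7b-5p and miR-467h, the 7 miRNAs called higher at E10.5 and over 2-fold above both interneurons at E12.5. Lower at both were miR-206-3p, miR-152-3p, miR-375-3p, miR-98-5p, miR-92a-1-5p and let-7d-3p. Of these 13, miR-7b-5p, miR-467h, miR-206-3p and miR-98-5p share reads with other rows. The 13 came from 154 called miRNAs considered at E12.5, 43 higher and 111 lower at E10.5. By the same rule, 1 of the higher and 10 of the lower miRNAs went the opposite way at E12.5. Several of the 13 were chosen after their values were seen. Across 332 miRNAs, which are not independent replicates, the ratios of the 2 stages had a Pearson r of 0.19 and a Spearman rho of 0.07, or 0.15 and 0.06 without the miR-218 family. The comparator differed between the stages, mixed GFP-negative cells at E10.5 and sorted interneurons at E12.5.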

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

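All tests in this part were chosen after the results were seen. In 11 miRNAs the E10.5 and E12.5 motoneuron contrasts went opposite ways: called in 1 direction at E10.5 and over 2-fold the other way against both interneuron libraries at E12.5. The difference was not tested, and the comparators differ between stages. miR-135a-5p was higher at E10.5 (log2 fold change 1.16, limma adjusted p = 0.0483) and lower at E12.5 (log2 ratio over the mean of both interneurons -1.51). The other 10 were lower at E10.5 and higher at E12.5: miR-369-3p (E12.5 log2 ratio 2.74), miR-378d (2.47), miR-665-3p (1.97), miR-411-3p (1.87), miR-17-3p (1.80), miR-1a-3p (1.76), miR-1188-5p (1.62), miR-409-5p (1.55), miR-3072-3p (1.42) and miR-433-3p (1.21). Their E10.5 log2 fold changes ran from -3.95 (miR-1a-3p) to -0.53 (miR-433-3p), where the median over all tested miRNAs was -0.34 and depended on the scaling. Of these 10, 5 belong to the Dlk1-Dio3 list, miR-369-3p, miR-665-3p, miR-411-3p, miR-409-5p and miR-433-3p. miR-1188-5p and miR-3072-3p are not on that list. The hairpins of the list span 109563692 to 109743795 on chromosome 12. Mir1188 lies within, starting at 109611822 in an intron of Rian, and Mir3072 lies past the end, starting at 109747878 in an exon of Mirg. miR-1a-3p, miR-378d and miR-411-3p share reads with other rows.

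Mesenchymal miRNAs were far lower in E10.5 motoneurons than in GFP-negative cells. Scaling was argued against: the member with the smallest fall still had a log2 fold change of -3.54 under the other scalings. Shared reads were too, since the 6 members that share reads with no other row had a median of -5.80. Mesenchymal cells among the GFP-negative cells stay open: all 10 members were lower, but that restates the pattern and decides nothing. A difference between motoneurons and other neural cells stays open as an untested biological explanation. At E12.5 the list summed to 199, 249 and 310 TPM in motoneurons, V2a and V3. A difference of the E10.5 size was thus not seen against these 2 interneuron populations. They are single libraries of another stage and table, and other neural cells were not sorted, so they cannot decide it for E10.5.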

How the results depend on the processing

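Totals without the mesenchymal and muscle lists, summed bundles, TMM factors on RPM and removal of other cell types' lists were chosen after seeing the data, and the other alternatives before. The E10.5 count of 208 ranged from 160 to 233 under other settings, and from 147 to 168 with 1 library left out. The log2 fold change of miR-218-5p stayed between 4.62 and 5.14 and past the threshold. Under quantile normalization 7 lists were called, among them the list of earlier motoneuron literature, which was not called in the main fit. With fry, the neural progenitor (adjusted p = 0.169), Hox (0.0922) and muscle (0.0544) lists did not pass. The list of earlier motoneuron literature did (fry adjusted p = 0.00893). The other lists called by camera in the main fit also passed with fry. The 11 called lists became 0 with an estimated correlation, where 4 libraries leave few degrees of freedom. With 1 arm per hairpin they became 6, and with bundles summed 8. They became 9 with totals without the mesenchymal and muscle lists, where the progenitor and muscle lists lost their calls (camera adjusted p = 0.0599 for both). They became 8 to 10 with 1 library left out and 12 with 3 other scalings or no filter, where the list of earlier motoneuron literature was gained; the cause was not tested. miR-10b-5p (-0.66) and let-7e-5p (0.60) reversed under quantile normalization. Of 973 other values for 59 named E10.5 miRNAs, 894 kept direction and side of the threshold. Settings in which a named miRNA was not tested are not among the 973. For E12.5, 55 of 186 values of named miRNAs and 19 of 127 list medians moved by over 0.5 log2 units. Most of these moved against 1 interneuron library alone or with another pseudocount. Without motoneuron replicate 1 or 2, the calls of miR-92a-3p, miR-7a-5p, miR-7b-5p, miR-92b-3p, miR-100-5p and miR-541-5p ended, and without replicate 2 those of miR-99a-5p, miR-127-3p and miR-126a-3p; without either non-motoneuron replicate, those of miR-3085-5p and miR-302c-3p did. Calls also ended for miR-219a-5p (without motoneuron replicate 1 or non-motoneuron replicate 2), miR-92b-3p (without non-motoneuron replicate 2) and miR-3078-3p, miR-7a-5p, miR-7b-5p and miR-126a-3p (without non-motoneuron replicate 1). The let-7 list lost its call without motoneuron replicate 1 (camera adjusted p = 0.0842) and without non-motoneuron replicate 1 (0.0679) or 2 (0.196), the Hox list without non-motoneuron replicate 2 (0.0859), the neural progenitor list without motoneuron replicate 1 (0.0707) or non-motoneuron replicate 2 (0.217) and the miR-17~92 list without motoneuron replicate 2 (0.0828).

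The replicate block gave 229 calls (67 higher, 162 lower) and 10 lists, without the muscle list (0.0516); deviations of same-numbered libraries had a correlation of 0.26, and no label says that the numbers pair. DESeq2 and edgeR fits were not run, since the table holds no counts.

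E12.5 counts higher and lower in motoneurons, higher in V2a and higher in V3 were 9, 5, 14 and 5. They became 61, 36, 58 and 22 with a fold rule of 2; 5, 0, 3 and 1 with a fold rule of 8; 21, 10, 36 and 12 with a minimum of 1 TPM; and 3, 1, 7 and 3 with a minimum of 100. A pseudocount of 10 gave 3, 0 and 7 for the first 3, and 0.1 gave 13 lower in motoneurons. Median of ratios and TMM factors each gave 8 for V2a. Against V2a alone 24 were higher and 30 lower in motoneurons, against V3 alone 43 and 18. Looser rules pass more miRNAs by construction; the cause of the other shifts was not tested. The r between stages ranged from 0.09 (V2a alone) to 0.24 (V3 alone), and from 0.18 to 0.20 with 1 E10.5 library left out. Single libraries limit E12.5, and depth limits miRNAs near 3 reads.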

Other observations

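All tests in this part were chosen after the results were seen. The V2a-high miRNAs at E12.5 included neighbours on chromosome 11, named after their values were seen. miR-216b-5p was at 4903 TPM in V2a, 722 in motoneurons and 495 in V3, miR-217-5p at 951, 207 and 59.8, and miR-216a-3p at 529, 126 and 84.2. Mir216b starts at 28746191, Mir216a at 28757012 and Mir217 at 28763728, all on the plus strand. miR-344h-3p, related by name to the V2a-leading miR-344e-3p, was at 36.3 in V2a, 7.04 in motoneurons and 7.21 in V3. miR-196b-5p, from a Hox cluster, was at 35.5 in V2a against 238 in motoneurons and 297 in V3, and miR-212-5p was at 1.88 in V3 against 46.8 in motoneurons and 20.6 in V2a. miR-216b-5p and miR-196b-5p lie in bundles of several rows.

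The passenger strands of the 2 miR-218 hairpins differed in reads between the E12.5 libraries. Motoneurons had 9 reads of miR-218-1-3p and 62 of miR-218-2-3p, V2a had 8 and 0, and V3 had 9 and 3 (Fisher's exact test, two-sided, motoneurons against V2a and V3 together, p = 2.14e-09, adjusted 8.56e-09 over 4 tests). It compares these libraries, not conditions, and covers counting error only, since PCR copies are not independent molecules. Carry-over of motoneuron RNA was argued against as the source of miR-218-1-3p in interneurons: V2a and V3 had 0.70 and 0.85 of its motoneuron level (95% counting intervals 0.23 to 2.03 and 0.30 to 2.40) but at most 0.073 of that of miR-218-5p. Shared reads were argued against, since values lay within 0.0038 of whole reads. As a hypothesis, Mir218-1 in Slit2 may be used in interneurons too and Mir218-2 mainly in motoneurons, but E10.5 held too few reads to tell (6 and 78 in motoneurons, 0 and 3 in GFP-negative cells, Fisher's exact test p = 1).

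miR-92a-3p stood at 36073 RPM in E10.5 motoneurons and 58245 in GFP-negative cells but at 112, 71.0 and 54.7 TPM in E12.5 motoneurons, V2a and V3, in tables that were scaled separately. A fall of the whole miR-17~92 transcript between stages was argued against as the sole cause: miR-92a-3p fell by 4.58 log2 units more than the farthest of 5 other arms, whose falls ran from 0.64 to 3.75. Different processing or sequencing of the tables could contribute. Of 71 miRNAs above 1000 RPM in all E10.5 libraries, 3 were over 50-fold lower in each E12.5 library, miR-92a-3p, miR-106a-5p and miR-30e-5p. miR-106a-5p shares reads with miR-20a-5p, the farthest of the 5 other arms, so its level is uncertain. Stage and table cannot be told apart here.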
